A study of Mus musculus with 2 samples.

How the data were processed

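H3K4me2 ChIP-seq was done on limb tissue of B6NCrl mouse embryos at day 13.5, from pooled males and females, in 2 biological replicates that the labels number 1 and 2 and tie to different tissue samples. Whether the tissue samples came from separate litters is not stated in the labels, so the spread between the replicates may include little variation between animals. The authors deposited 4 peak lists on the mm10 assembly in the narrowPeak format, per the file headers and notes deposited with them. Peaks were called in each replicate alone against a control file, and in both replicates pooled, per the deposited notes. A further list of replicated peaks was derived from the pooled list and both replicates' lists, per the deposited notes. Every replicated peak has the coordinates of a pooled peak. The aligner, the peak caller, their versions, the threshold and the read depth are not given in the sources used here.

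The signal value of each peak is a score that the authors' peak caller gave, and whether it is a fold over control is not stated, so it was used only to describe and rank peaks. The deposited lists give −log10 of a p-value and −log10 of a q-value for each peak, again the authors' own. The smallest −log10 p in the lists was 2.03, 2.07, 2.00 and 2.00 for replicate 1, replicate 2, the pooled and the replicated list. Weak and narrow peaks near this threshold are the least certain, and a region without a peak was below it in that library. Since depth is unknown, no detection limit can be set for a region. Peaks were called on the reads of each library separately, so covered length can move with depth as well as with the mark.

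Gene positions came from GENCODE vM21 and sequence from GRCm38, which is mm10, and the 21 main chromosomes were analysed. Overlaps, covered bases and statistics were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and lists were shuffled with bedtools 2.31.1. Positions are 1-based. A promoter peak of a gene overlaps the 1 kb either side of the outermost annotated 5′ end of the gene, which for genes with distant alternative starts can lie far from the start used in a tissue. Covered length is the number of bases under peaks within 10 kb either side of that end, at most 20001 bp. Protein-coding genes numbered 21938, and all 426 fixed list genes were found among them.

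Before the data were examined 22 lists were fixed: limb patterning regulators, hedgehog, FGF, BMP and Wnt pathway, cartilage, bone, skeletal muscle, tendon and connective tissue, surface ectoderm, endothelium, erythroid cells, macrophages, Schwann cells, central neurons, liver, heart, gut, lung and pancreas, germ cells, ribosome and proteasome, the 4 Hox clusters and olfactory receptors. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test in each replicate, with Benjamini-Hochberg adjustment over the 22 lists, and a call needed an adjusted p under 0.05 in both replicates. Genes are not independent replicates, so these p-values describe the libraries. The median covered length of a list was placed among 10000 random lists of the same size with a fixed seed and called where the percentile was above 97.5 or below 2.5 in both replicates. The lowest and highest percentiles that a list could reach among CpG-matched lists were computed after the data were seen. Some lists overlap, and neighbouring genes can share a window. The lists' plot shows the middle 95% of 1000 random lists. Domains were replicated peaks merged over gaps of up to 1 kb. For sequences at distal summits, fixed consensus sequences were sought on both strands within 150 bp of the summits of replicated peaks over 1 kb from any transcript start and in windows 2 kb away outside all peaks, matched on GC content in bins of 1%. Each share has an exact binomial interval, which covers counting error only, and the reversed, not complemented, consensus served as a control. The count of sequences whose intervals lay apart was defined after the data were seen.

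The genes named were fixed by rule: of each list the 3 members with the largest covered length and up to 2 without a promoter peak, the genes in the 20 widest domains, the 10 genes with the largest difference between replicates, a set of anchor genes, and the genes nearest to the 10 strongest distal peaks found in both replicates. Single Hox genes named in the account of the clusters, and flanking genes of the gene-poor intervals in the closing observations, were chosen after their values were seen.

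Simulated data had the real number of genes, 1 library and lists of 25 genes, as many as the skeletal muscle list. Lists of which 95% of members were marked were called 98% of the time. Lists marked at 30% were called 87% of the time and unchanged lists 2%. The real lists had 9 members or more and needed both replicates, so these rates do not describe the shorter lists. In a separate simulation of lists of 20 genes, lists with doubled covered length were found 94% of the time. There 3% of lists without an effect fell outside the bounds. Those lengths were drawn from a smooth distribution, without the many values of 0 in the real data. Planted sequences were found in 100% of windows.

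Alternatives set before the data were examined were other overlap rules, peaks kept at a −log10 q of at least 2 or 5, equal numbers of peaks, promoter windows of 500 bp and 2 kb, any annotated transcript start, covered windows of 5 and 2 kb, random lists matched on promoter CpG or drawn from genes with a promoter peak, other merging gaps, a 75 bp window and flanks not matched on GC for the sequences, and leaving out each replicate. Peaks on unplaced scaffolds were left out of the comparisons.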

Results

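Dimethylated lysine 4 of histone H3 (H3K4me2), a chromatin mark found at promoters and enhancers, was mapped by ChIP-seq in limbs of mouse embryos at day 13.5 of development. At this stage the digits are forming, cartilage has condensed and muscle is differentiating. The labels give 1 group of 2 biological replicates, each from pooled male and female B6NCrl embryos, and do not separate forelimb from hindlimb. Peaks were called in each replicate alone and in both pooled, on the mm10 genome. Replicate 1 had 59767 peaks over 60.2 Mb, 2.27% of the sequenced genome, and replicate 2 had 59041 peaks over 59.0 Mb, 2.23%. The pooled list held 63084 peaks and the authors' replicated list 45432. Read depth is not given in the sources used here, so a region without a peak was below the calling threshold and is not shown to lack the mark. With a single group, the comparisons are between replicates, between gene lists fixed before the data were examined, and between regions. Values after ± are SD over the 2 replicates, and covered length means the bases under peaks within 10 kb either side of the 5′ end of a gene.

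The first comparison asked which groups of genes carried the mark. Limb patterning regulators, the transcription factors and signals that set the limb axes, carried it most broadly outside the Hox clusters, with a median covered length of 11.9 ± 0.034 kb (SD, n = 2). Components and targets of the hedgehog, FGF, BMP and Wnt pathways followed with 8.09 ± 0.115 kb, tendon and connective tissue genes with 6.28 ± 0.091 kb, and cartilage genes with 4.65 ± 0.152 kb. Genes of macrophages, red blood cells, germ cells and liver had medians of 0.27 ± 0.011, 0.331 ± 0.0057, 0.19 ± 0.138 and 0 kb. Over all 21938 protein-coding genes the median was 2221 bp in replicate 1 and 2177 bp in replicate 2.

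Of the 42 limb patterning regulators, 41 had a promoter peak, within 1 kb of the 5′ end, in each replicate. Among other genes 65.8% and 65.7% did (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 7.74e-06 and 3.80e-06). Against random lists matched on promoter CpG content, added after the data were seen and marked at 94.6% of members, the share lay at percentiles 87.7 and 87.9 and did not pass. Hoxa11, Hoxa10 and Hoxa9, 5′ Hox genes that pattern limb segments, were covered over 20.0 kb (both replicates), 19.9 ± 0.033 and 19.8 ± 0.033 kb of the window. Tbx5, the forelimb identity factor, had 14.8 ± 0.074 kb, and Tbx4 and Pitx1, which act in the hindlimb, had 11.4 ± 0.061 and 11.6 ± 0.033 kb. Hand2, an upstream activator of Shh in the posterior limb bud, had 18.0 ± 0.064 kb, and Lmx1b, the dorsal limb determinant, had 18.2 ± 0.249 kb. Shh itself, made in the posterior limb bud, had 5.69 ± 0.05 kb, and Fgf8, a signal of the apical ectodermal ridge, had 6.79 ± 0.313 kb. Fgf10, the mesenchymal signal for limb outgrowth, was the member without a promoter peak, although a peak lay at another annotated start of the gene in both replicates. The list holds 9 Hox genes. Its other 33 members, taken alone after the data were seen, had a median of 10.2 ± 0.122 kb, still at percentile 100 of random lists.

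All 31 genes of the signalling list had a promoter peak in both replicates (adjusted p = 1.84e-05 and 1.46e-05 by Fisher's exact test), a share that did not pass against CpG-matched random lists (percentiles 82.1 and 82.3), where no share could have passed. Id3, a BMP target, had 13.0 ± 0.384 kb covered, Axin2, a feedback inhibitor of Wnt signalling, had 11.9 ± 0.284 kb, and Wnt5a, a ligand of the distal limb, had 11.9 ± 0.277 kb. Ptch1, the hedgehog receptor and a target of the pathway, had 10.8 ± 0.137 kb.

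Among skeletal lineages, 24 of 26 cartilage genes had a promoter peak in each replicate (adjusted p = 0.00673 and 0.0067, Fisher's exact test). Sox9, the master regulator of cartilage, had 9.01 ± 0.052 kb covered, and Sox6, which acts with it, 12.9 ± 0.337 kb. Col2a1, the main cartilage collagen, had 7.54 ± 0.303 kb and Col9a3 10.1 ± 0.083 kb. Col10a1, a collagen of hypertrophic cartilage, had no covered base, and Ucma, a cartilage matrix gene, had 195 bp in replicate 1 and 0 in replicate 2. Pth1r, the parathyroid hormone receptor of growth-plate cartilage, had 9.31 ± 0.035 kb, in a window shared with its neighbour Myl3. Its own promoter peak was weak, with the authors' −log10 p at 4.51 and 5.79 in replicates 1 and 2. Of 13 bone genes 7 had a promoter peak in each replicate (adjusted p = 0.427 and 0.418, Fisher's exact test), and their median covered length was 2103 bp in replicate 1 and 1443 bp in replicate 2. Col1a1, the main bone collagen, had 12.1 ± 0.116 kb and Satb2 8.55 ± 0.182 kb, whereas Dmp1, made by osteocytes, had none.

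Tendon and connective tissue genes had a promoter peak at 19 and 18 of 20 members, which passed the test in replicate 1 and missed it in replicate 2 (adjusted p = 0.0076 and 0.0514, Fisher's exact test). Their covered length was at percentile 100 of 10000 random lists in both. Zfhx4 had 16.2 ± 0.121 kb, Pdgfra, a receptor of mesenchymal cells, 14.5 ± 0.303 kb, Ebf1 12.4 ± 0.904 kb and Scx, the tendon transcription factor, 10.2 ± 0.086 kb. Tnmd, a late tendon marker, had no covered base. Skeletal muscle genes did not pass, with promoter peaks at 18 and 19 of 25 (adjusted p = 0.674 and 0.418, Fisher's exact test) and a median of 2.99 ± 0.018 kb. Six1 and Lbx1, regulators of muscle precursors, had 8.33 ± 0.018 and 7.90 ± 0.351 kb, and Myod1 and Myog, which commit cells to muscle, 2.49 ± 0.115 and 2.96 ± 0.083 kb. The promoter peak of Myog was weak, with the authors' −log10 p at 4.37 and 4.72 in replicates 1 and 2, against 24.4 and 46.5 at Myod1. Acta1 and Myh3, which encode contractile proteins, had no promoter peak and 2.00 ± 0.198 and 0.892 ± 0.228 kb covered nearby.

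Surface ectoderm genes had a promoter peak at 21 of 22 members in each replicate (adjusted p = 0.00667 and 0.00668, Fisher's exact test) and a median of 3.68 ± 0.054 kb. Tfap2a, an ectodermal transcription factor, had 11.9 ± 0.214 kb, Cldn6, an epithelial claudin, 9.51 ± 0.073 kb and Sp8, needed for the apical ridge, 7.40 ± 0.2 kb. Trp63, the epidermal regulator, had 0.41 ± 0.101 kb around the outermost annotated 5′ end, which can lie far from the start a tissue uses. Schwann cell genes had 11 of 12 promoters marked (adjusted p = 0.0902 and 0.0899, Fisher's exact test), and their median of 4.14 ± 0.259 kb lay at percentiles 99.25 and 99.78. Tfap2b and Ngfr, both active in the neural crest lineage, led that list with 11.2 ± 0.039 and 7.19 ± 0.419 kb, and Plp1, a myelin gene, had none. Endothelial genes had 16 and 15 of 20 promoters marked (adjusted p = 0.278 and 0.484, Fisher's exact test) and 2.88 ± 0.116 kb. Fli1 and Erg, transcription factors of the vessel wall, had 10.3 ± 0.163 and 7.18 ± 0.069 kb, and Emcn, an endothelial sialomucin, had none.

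Genes of macrophages, red blood cells, liver and germ cells and the olfactory receptors carried fewer promoter peaks than other genes. Against CpG-matched random lists this held for liver, germ cell and olfactory receptor genes and ended for macrophage (percentiles 6.69 and 6.58) and erythroid genes (58.5 in both replicates). Macrophage genes had 2 of 16 (adjusted p = 6.04e-05 and 6.22e-05, Fisher's exact test), where Cd68 had 7.15 ± 0.711 kb and Adgre1 none. The promoter peak of Cd68 was weak, with the authors' −log10 p at 8.81 and 5.09 in replicates 1 and 2. Erythroid genes had 6 of 19 (adjusted p = 0.00673 and 0.0067, Fisher's exact test). Klf1 and Epor, a regulator and a receptor of red cell precursors, had 6.77 ± 0.325 and 4.10 ± 0.193 kb, and Alas2 and Epb42, used in later red cells, had none. Liver genes had 3 and 2 of 20 (adjusted p = 1.84e-05 and 2.66e-06, Fisher's exact test), and Alb and Afp, the major plasma proteins, had no covered base. Germ cell genes had 3 and 5 of 18 (adjusted p = 8.16e-05 and 0.00523, Fisher's exact test), with Nanos3 the broadest at 8.40 ± 0.421 kb. Of 1134 olfactory receptor genes, which act in nasal sensory neurons, 3 had a promoter peak in each replicate. Their CpG-matched random lists were themselves marked at only 2.85% and 2.70% of members. Those lists could hold olfactory receptor genes themselves, which lowers these shares.

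Central neuron genes had 21 of 25 promoters marked in each replicate (adjusted p = 0.0819 and 0.0825, Fisher's exact test), with a median of 2.89 ± 0.1 kb. Emx2, which is also a limb and girdle regulator, had 13.9 ± 0.455 kb, and Neurod1, a neuronal differentiation factor, 2.11 ± 0.11 kb. Heart genes had 10 and 9 of 18 (adjusted p = 0.478 and 0.246, Fisher's exact test), with Hand1 at 7.98 ± 0.161 kb and Myl3 at 12.8 ± 0.118 kb in the window it shares with Pth1r. Gut, lung and pancreas genes had 9 of 20 (adjusted p = 0.0819 and 0.0825, Fisher's exact test). Foxa3 and Foxa1, endodermal transcription factors, had 4.68 ± 0.288 and 4.59 ± 0.502 kb, and Gcg, which encodes glucagon, had none. Ribosome and proteasome genes, used in every cell, had 39 and 40 of 40 (adjusted p = 1.47e-05 and 8.53e-07, Fisher's exact test) and a median of 3.57 ± 0.202 kb. Their promoter share lay at percentiles 92.8 and 99.4 of CpG-matched random lists and did not pass.

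In covered length 11 of the 22 lists lay above the middle 95% of 10000 random lists in both replicates: limb patterning, signalling, cartilage, tendon, surface ectoderm, Schwann cells, ribosome and proteasome, and the 4 Hox clusters. Erythroid cells, macrophages, liver, germ cells and olfactory receptors lay below it. Some calls depended on the setting. Surface ectoderm lost its call with windows of 5 and 2 kb either side (mean percentiles 92.8 and 73.5) and against random lists of marked genes (74.0), Schwann cells with 2 kb (81.0) and ribosome genes against marked genes (96.7). The short call of erythroid genes ended with 2 kb (2.85, although the median was 0), at a −log10 q of at least 5 (2.53) and against marked genes (25.4). Calls were also gained. Bone genes with a promoter peak, at a median of 7335 bp, passed as long against marked genes (99.97), and gut, lung and pancreas genes passed as short with 2 kb (1.65). Against random lists matched on the CpG content of their promoters, the call ended for the short erythroid (percentiles 83.7 and 84.9), macrophage (54.0 and 56.4), liver (9.09 and 9.38) and olfactory lists and for the ribosome list (99.25 and 96.7), while skeletal muscle genes passed as long (99.5 and 99.6), although with windows of 5 and 2 kb they lay at mean percentiles of 29.2 and 15.3 of unmatched lists. For these short lists the matching could not have kept the call, since in replicate 1 even a median of 0 would lie at percentile 37.5 for erythroid, 18.2 for macrophage, 9.0 for liver and 50 for olfactory receptor genes. Matching in the same way, added after the data were seen, ended the promoter calls of erythroid and macrophage genes and those of limb patterning, signalling, ribosome and HoxA genes, for which matched lists were themselves marked at 94.6, 97.4, 93.6 and 98.6% of members in replicate 1. Under this matching tendon genes (percentile 100 in both replicates) and Schwann cell genes (99.96 and 99.97) passed as marked more often, gut, lung and pancreas genes passed as marked less often (0.965 and 0.945), and cartilage and surface ectoderm genes kept their calls. The promoter call of surface ectoderm ended with a 500 bp window (84.1%), that of cartilage ended for peaks at a −log10 q of at least 5 (80.8%), and central neuron genes passed with any annotated start (96.0%) and with a 2 kb window (92.0%). Tendon genes passed in both replicates with a 500 bp window (92.5%) and for peaks at a −log10 q of at least 2 (92.5%) and 5 (larger adjusted p = 0.0387, Fisher's exact test).

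**Figure D1:**
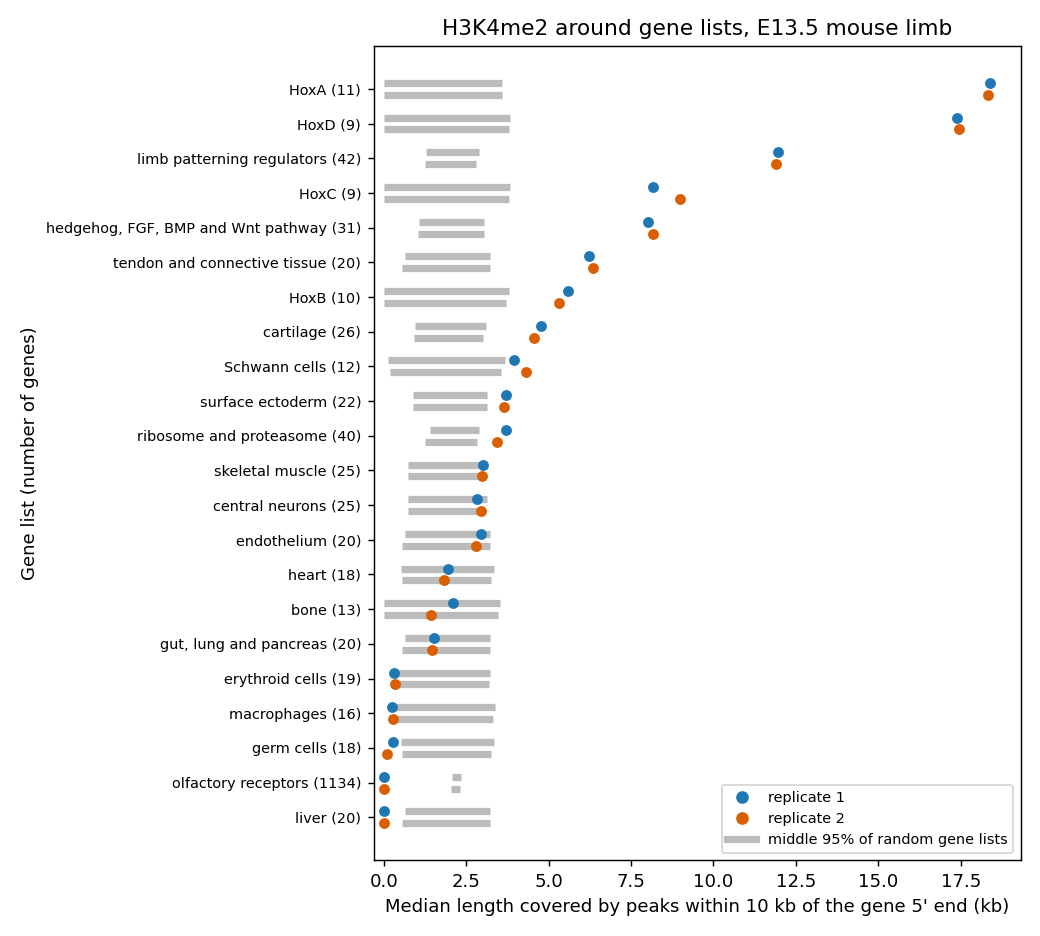
Median length covered by H3K4me2 peaks within 10 kb of the gene 5′ end (kb, horizontal axis) for each gene list (vertical axis, number of genes in brackets), with a point for each replicate and grey bars for the middle 95% of random gene lists of the same size. HoxA, HoxD and limb patterning genes lie farthest to the right, at 18.4, 17.4 and 11.9 kb, and liver and olfactory receptor genes lie at 0.

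The Hox clusters, which encode position along the body and limb axes, differed in how much of their length was marked. Peaks covered 73.2 ± 1.64% of HoxA (SD, n = 2; chromosome 6, 52155590 to 52260880), 53.0 ± 0.554% of HoxD (chromosome 2, 74668310 to 74765142), 49.3 ± 3.17% of HoxC (chromosome 15, 102921103 to 103036852) and 19.5 ± 0.414% of HoxB (chromosome 11, 96194316 to 96368256). The HoxB span, the longest at 173.9 kb, includes a long interval from Hoxb13 to Hoxb9 (96197447 to 96271457) without another Hox gene. Its percentage is therefore not fully comparable with the others. In HoxD the bodies of Hoxd9, Hoxd10 and Hoxd12 were covered over 100% of their length, Hoxd13, the gene of the digit region, over 97.0 ± 0.43%, Hoxd11 over 97.7 ± 1.26% and Hoxd8 over 95.3 ± 0.746%. Hoxd4, Hoxd3 and Hoxd1 at the 3′ end had 32.5 ± 0.156%, 24.5 ± 0.354% and 48.6 ± 12.7%, and the annotated Hoxd3 and Hoxd4 bodies overlap.

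HoxA showed nearly unbroken coverage from Hoxa6 to Hoxa13, with 95.4 ± 0.378% of the body of Hoxa6, 99.0 ± 0.0088% of Hoxa9, 100% of Hoxa11 and 95.9 ± 0.044% of Hoxa13. Toward the 3′ end Hoxa5 had 76.0 ± 0.574%, Hoxa2 84.2 ± 7.5% and Hoxa1 35.1 ± 9.88%, with 61.2% and 68.8% of Hoxa4 and 51.8% and 48.3% of Hoxa3 in replicates 1 and 2. The annotated Hoxa3 body contains those of Hoxa4, Hoxa5 and Hoxa6, so its value in part repeats theirs. In HoxC, Hoxc11 was covered over 100% and Hoxc10 over 84.1 ± 0.194%, whereas Hoxc13 had 24.6 ± 0.541% and Hoxc4 15.9 ± 0.422%. In HoxB, Hoxb8 had 74.3 ± 2.67%, Hoxb4 70.0 ± 6.12% and Hoxb13, which is separated from the rest of its cluster, 9.79 ± 4.67%. Every HoxA, HoxC and HoxD gene had a promoter peak in both replicates, and Hoxb3 was the only HoxB gene without a peak at its outermost start. By Fisher's exact test HoxA passed (adjusted p = 0.0375 and 0.041), though not against CpG-matched random lists (percentiles 57.2 and 56.9), where no share could have passed, while HoxC and HoxD, with 9 of 9 each, did not (0.0516 and 0.0514 for both), nor did HoxB with 9 of 10 (0.22 and 0.22). Neighbouring Hox genes share windows, so their values are not separate measurements. HoxB, at 5.45 ± 0.186 kb the shortest of the clusters in median covered length, lay at a mean percentile of 32.7 among random lists when the window was narrowed to 2 kb either side.

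**Figure D2:**
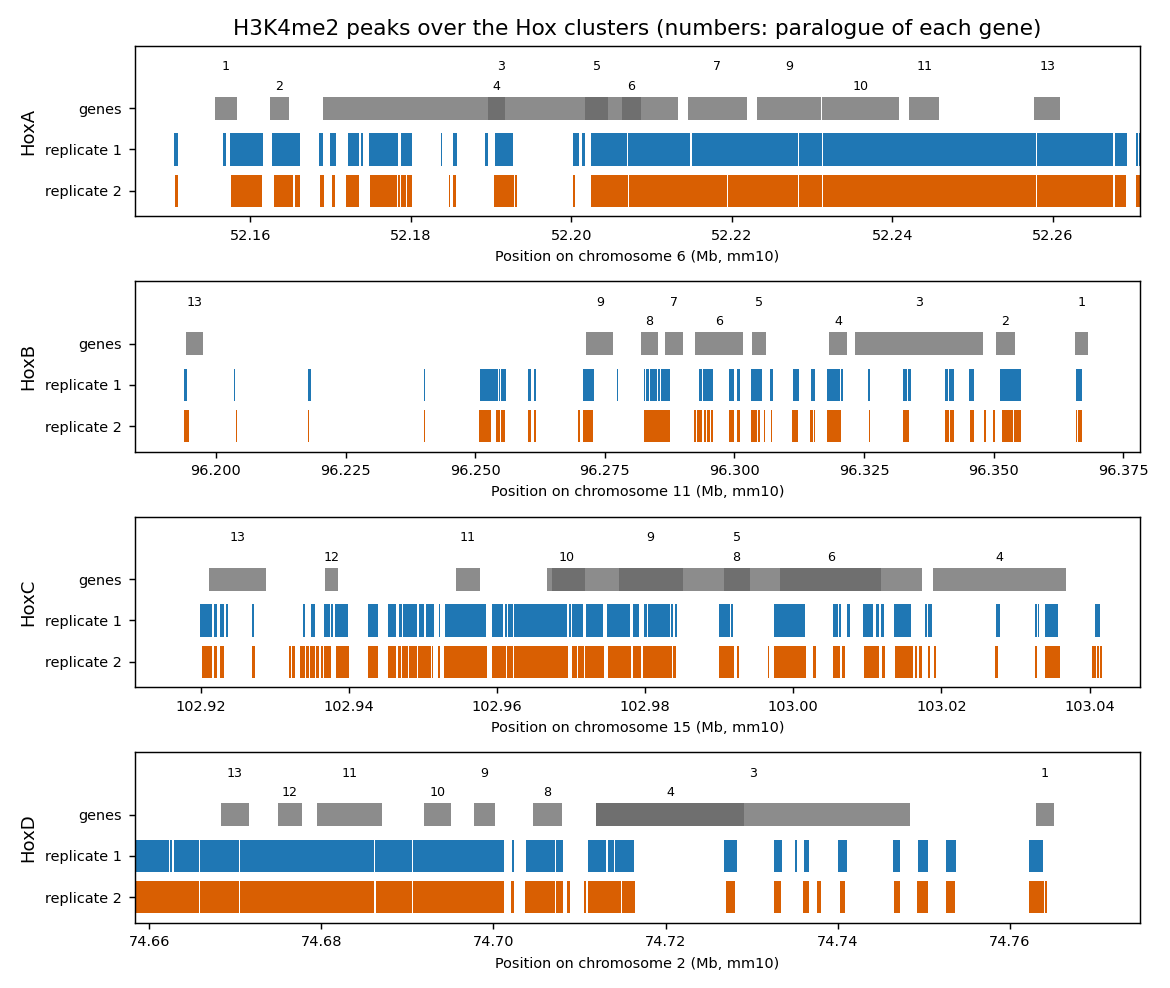
H3K4me2 peaks of replicate 1 (blue) and replicate 2 (orange) over the HoxA, HoxB, HoxC and HoxD clusters, with gene bodies in grey, the paralogue number above each gene, and the position on the chromosome in Mb on the horizontal axis. Peaks run without long gaps over the 5′ genes of HoxA and HoxD, which were covered over 73.2% and 53.0% of the whole cluster. They are scattered over HoxB, covered over 19.5% of a span that includes the long interval from Hoxb13 to Hoxb9.

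The widest marked domains lay over the HoxA, HoxD and HoxC clusters. When peaks of the replicated list were merged over gaps of up to 1 kb, the widest domain spanned 68982 bp from Hoxa5 past Hoxa13 (chromosome 6, 52200183 to 52269164), of which replicates 1 and 2 covered 97.2% and 95.8%. The second spanned 54838 bp from Evx2, the neighbour of the HoxD cluster, to Hoxd9 (chromosome 2, 74647535 to 74702372; 93.8% and 94.7%), and the third 39001 bp over Hoxc11, Hoxc10 and Hoxc9 (chromosome 15, 102945295 to 102984295; 82.8% and 87.2%). Next came a domain of 32631 bp inside the annotated span of Zfhx3 (chromosome 8, 108694502 to 108727132), whose outermost start lies at 107942644. Other annotated starts of the gene can lie nearer. It was followed by 27029 bp at Ebf3, 25638 bp at Nr2f2, a nuclear receptor of mesenchyme and vein, 24374 bp at Hand2 (chromosome 8, 57311603 to 57335976) and 23604 bp at Lmx1b (chromosome 2, 33626217 to 33649820). Ptch1 had 22594 bp, Tbx5 20918 bp, Bahcc1 20379 bp, Bcl9l 20168 bp, Fgfr2, an FGF receptor of limb ectoderm, 19366 bp, Zfhx4 19303 bp, Lhx9, a distal limb regulator, 18529 bp, Emx2 18094 bp, Prdm16 18046 bp, Rarg, a retinoic acid receptor of cartilage, 17811 bp, Tbx15 17705 bp and Tfap2a 17510 bp. Of 37279 domains, whose median width was 1194 bp, 175 reached 10 kb. The ranking depended on the merging gap. Of these 20 domains, 10 were again among the widest 20 with no merging and 12 with merging over 3 kb, and the widest domain was then 26560 and 74754 bp.

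Peaks were concentrated at promoters. Each peak was counted once, in the order of priority promoter, exon, intron and intergenic sequence. Of the peaks, 40.2 ± 0.206% (SD, n = 2) overlapped a promoter, within 1 kb of an annotated transcript start. A further 6.26 ± 0.0042% overlapped an exon but no promoter. Those in an intron that touched neither made up 30.2 ± 0.135%, and 23.4 ± 0.075% were intergenic. Promoters held 8.65 ± 0.066 times the covered bases that their share of the genome would give, and intergenic sequence 0.293 ± 0.0024 times. A promoter peak was found at 65.8 ± 0.055% of protein-coding genes, of which 14287 had it in both replicates, 151 in replicate 1 only, 134 in replicate 2 only and 7366 in neither. On the X chromosome, which carries Tnmd, Plp1 and Alas2, the share was lower, at 50.8% in replicate 1 and 50.4% in replicate 2. The promoter share of peaks rose to 54.8% when peaks were kept at a −log10 q of at least 5.

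Away from promoters, 24616 peaks of the replicated list, 54.2%, were distal and had a median signal value of 4.66, against 32.9 at promoters. The strongest distal peak found in both replicates lay 2.41 kb upstream of Macf1, a cytoskeletal linker gene (chromosome 4, 123685427 to 123687918, intergenic), with signal values of 64.3 and 66.0. Others lay in an intron of Plxnb2, a semaphorin receptor (chromosome 15, 89172239 to 89175303; 64.1 and 59.9), and 15.9 kb from Cldn9 in intergenic sequence (chromosome 17, 23699105 to 23700614; 59.6 and 63.2). An exon of Klhl31, a muscle gene, held a peak with values of 59.9 and 59.6 (chromosome 9, 77654803 to 77656224). A peak 76.1 kb from Hmga2, a growth regulator of embryonic mesenchyme, had values of 60.9 and 51.0 (chromosome 10, 120550965 to 120553770), and an intron of Phactr1, 236 kb from its outermost start, held one with 56.0 and 55.9 (chromosome 13, 42915841 to 42918056). Signal values are the authors' own for each list and rank peaks within it.

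Of the binding sequences sought, 10 were, with intervals apart, more frequent at distal summits than in GC-matched sequence 2 kb away, in 19102 windows of each. The homeobox core TAATTA was within 150 bp of 8.47% of summits (95% exact binomial interval 8.08 to 8.87) and in 4.55% of flanks (4.26 to 4.85), a ratio of 1.86, and its reversed sequence had a ratio of 1.57. The HOX13-type sequence had 1.58 against 1.36 when reversed, and the TEAD sequence 1.18 against 0.908. The ETS sequence, which contains a CpG while its reversed form does not, had 1.92 against 0.80. The MEF2 sequence had 1.72 against 1.38. The reversed ratio exceeded that of the sequence itself for SOX (1.25 against 1.09), CTCF (1.97 against 1.28, where the reversed form contains a CpG) and, by little, LEF/TCF (1.30). The SP sequence, with a CpG in both forms, had 1.91 and 1.80 reversed, and the E-box 1.38 and 1.84, where the reversed form contains a CpG. Sequences for GLI (0.793, reversed 0.774), RUNX (0.833, reversed 0.841) and PITX (0.831, reversed 1.22) were rarer at summits. The summit windows held more CpG than the flanks, 2.13% against 1.24% of dinucleotides, at a GC content of 49.1% in both. Without GC matching the ratios for the homeobox, SOX, LEF/TCF, GATA and GLI sequences crossed 1, to 0.915, 0.942, 0.963, 0.685 and 1.18, and that for the HOX13-type sequence fell to 1.01. With windows of 75 bp either side, the sequences more frequent at summits with intervals apart from the flanks numbered 7 rather than 10, and the HOX13-type (1.41), CTCF (1.17) and MEF2 (1.58) sequences were the ones lost.

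The replicates were compared with each other to see which regions were found in both. Covered lengths in replicates 1 and 2 were 18393 and 18326 bp at Hoxa13, 11377 and 11463 bp at Tbx4 and 10092 and 10214 bp at Scx. The largest differences among all genes were at Meis2, a proximal limb regulator, with 14264 and 12139 bp, Chd2, a chromatin remodeller, with 8019 and 5975 bp, and Hoxc12 with 6428 and 8367 bp. Ldlrad3 had 5299 and 3479 bp, Wnt7b, a Wnt ligand, 7903 and 6132 bp and Tmem30b 4850 and 6572 bp. With 1 value per replicate these differences have no test.

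Of the peaks of replicate 1, 78.4% overlapped a peak of replicate 2 by at least 1 bp (95% exact interval 78.1 to 78.8), and 80.1% of those of replicate 2 overlapped replicate 1 (79.7 to 80.4). These intervals cover counting error over peaks only, not the spread between pairs of replicates. The Jaccard index of covered bases was 0.764. In 20 shuffles of replicate 2 within chromosomes, 4.79 ± 0.071% of replicate 1 peaks (mean and SD over shuffles) were overlapped, and the highest Jaccard index was 0.013. Peaks found in replicate 1 only numbered 12881, with a median width of 241 bp and 14.3% at promoters, and those in replicate 2 only 11771, with 232 bp and 13.8%. Shared peaks had median widths of 813 and 788 bp, with 47.1% and 46.9% at promoters. Across 46870 shared peaks, which are not independent replicates, the signal values had a Spearman correlation of 0.859. The authors' replicated list kept 72.0% of the pooled peaks, with a median signal value of 8.44 against 2.62 for those it left out, and 45.8% against 13.8% of them at promoters. Not every kept peak overlapped a peak of both replicates. Of 45417 on the main chromosomes, 42206 did, 1485 overlapped replicate 1 only, 1647 replicate 2 only and 79 neither. Among the peaks left out, 203 overlapped both.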

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

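The tests on the stronger peaks, on genome-wide coverage, on Tbx4 and Pitx1, on windows of like coverage, and on the percentiles within reach of a list were chosen after the result was seen. The CpG-matched covered length and the equal numbers of peaks were set as alternatives before the data were examined, but their use as tests of an explanation was chosen after their results were seen. The CpG-matched promoter shares and the windows covered over 20% were chosen after other results had been seen and before their own.

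Peaks outside the chromosomes analysed drew attention because the comparisons did not use them: the replicated list held 15 on unplaced or unlocalised scaffolds. Of these, 6 lay on a scaffold of the X chromosome that carries Spry3, Tmlhe and Vamp7, where replicates 1 and 2 had 6 and 8. There are no control peaks to set beside them, and no explanation was tested.

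Erythroid, macrophage, liver, germ cell and olfactory receptor genes had few promoter peaks and short covered length, and low promoter CpG content is a candidate explanation. Among random lists matched on CpG, the covered length of the germ cell list stayed low, at percentile 1.61 or below in both replicates. So did the promoter share of germ cell (0.015), liver (0.895) and olfactory receptor (0.0) genes, which argues against CpG content as the whole cause there. In replicate 1 the matched lists for germ cell, liver and olfactory receptor genes were marked at 55.9, 35.6 and 2.85% of members. The lists themselves were marked at 16.7, 15 and 0.265%, and other genes at 65.9, 65.9 and 69.4%. Matched lists were drawn from all genes of like CpG content, members of the list included. The 1134 olfactory receptor genes thus lower the share of their own matched lists. How much of their lack CpG content could account for is therefore not shown. For the separate pattern of long coverage at limb patterning genes, percentile 100 argues against CpG content as the whole cause. The explanation may hold for the promoter share of erythroid (58.5) and macrophage genes (6.69). In covered length the test could not decide for erythroid (84.9), macrophage (56.4), liver (9.38) and olfactory receptor genes (50), because even a median of 0 would lie above percentile 2.5 of their matched lists. Few cells of a type in the tissue would give the same low values, and cell composition was not tested.

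In replicate 1, 12881 peaks had no partner in replicate 2, and 11771 peaks of replicate 2 had none in replicate 1. The lists held 59751 and 59024 peaks, so their difference in length is far smaller than the number of peaks without a partner. With equal numbers of peaks 79.0% of replicate 1 peaks were overlapped. So few peaks were cut that this value could hardly have come out otherwise. Weak peaks remain a candidate explanation: at most 0.417% of the stronger peaks of a replicate, those above its median −log10 p, lacked a partner. These medians, 10.5 and 11.3, lie well above the calling threshold, so the split alone does not show that peaks without a partner lie near it. Peaks without a partner had a median −log10 p of 4.37 in replicate 1 and 4.47 in replicate 2. Shared peaks had 22.0 and 22.5. Of the 5976 replicate 1 peaks with the lowest −log10 p (2.03 to 3.73), 35.6% had a partner. In replicate 2 it was 37.5% of the 5903 lowest. Peaks without a partner thus tended to be weak. Of the peaks without a partner, 8.35% in replicate 1 and 11.3% in replicate 2 had a −log10 q of at least 5. Differences in depth stay open because depth is not given in the sources used here, and no biological explanation was tested, since both replicates belong to the same group.

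HoxC was covered over 51.6% in replicate 2 and 47.1% in replicate 1. HoxD was also covered slightly more in replicate 2 (53.4% against 52.6%), whereas HoxA and HoxB were covered less. Wider peaks throughout replicate 2 are argued against, since it covered fewer bases over the genome, a change of −1.89%. Chance differences between libraries are argued against by windows of the same length covered over 20%, where the HoxC difference lay at percentile 100 of 645 windows. However, HoxC was picked for its difference, and the windows overlap one another, so they stand for fewer separate regions. Among windows covered 35 to 65%, where it also lay at 100, only 21 were found, too few to decide. More hindlimb tissue in replicate 2 might raise the mark over HoxC, and Tbx4 and Pitx1, whose mean difference lay at percentile 61.5 of gene pairs of like coverage, neither showed nor excluded it. The labels do not separate forelimb from hindlimb.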

How the results depend on the processing

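The CpG-matched test of promoter shares, the limb patterning list without Hox genes, and the sequence and genomic distribution values for each replicate alone were chosen after other results of these data had been seen, as were the limits within which a Jaccard index or a correlation counts as unmoved. With 2 replicates, leaving out either returns the other's value, which says nothing on stability. Depth is not given in the sources used here, so its effect could not be tested. No paired analysis was possible because there is only 1 group. The cause of each shift below was not tested, except that a wider window or looser rule takes in more peaks by construction.

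Replicate overlap for replicates 1 and 2 was 72.2% and 74.4% when at least 50% of a peak had to be covered, 63.0% and 63.7% with reciprocal overlap, 90.5% and 88.0% at a −log10 q of at least 5, 83.0% for replicate 1 at 2 and 79.0% for replicate 1 with equal numbers of peaks. The Jaccard index was 0.779 and 0.823 at a −log10 q of at least 2 and 5. The correlation of signal was 0.951 with reciprocal overlap and 0.874 and 0.902 at these q-values.

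Promoter, exon, intron and intergenic shares of peaks were 36.3, 7.40, 32.2 and 24.1% with a 500 bp promoter window, 47.9, 4.50, 25.5 and 22.1% with 2 kb, 42.9, 6.15, 28.1 and 22.8% at a −log10 q of at least 2, and 54.8, 5.69, 19.5 and 20.0% at 5. Genes with a promoter peak were 64.5% and 67.2% with 500 bp and 2 kb, 69.3% with any annotated start, and 65.5% and 64.3% at a −log10 q of at least 2 and 5. At 5, HoxA, HoxB, HoxC and HoxD were covered over 71.3, 17.2, 43.7 and 52.2%.

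Without merging the widest domain had 26560 bp, and 10 of the 20 widest domains were found again, against 12 with 3 kb merging. Lists with short covered length numbered 1 rather than 5 with CpG-matched random lists, where even a median of 0 would not pass for erythroid, macrophage, liver and olfactory receptor genes, and 2 with random lists of marked genes, where macrophages and liver had too few marked members for a value. Covered length crossed the middle of random lists for HoxB (1282 bp), endothelium (1570 bp), central neurons (1542 bp) and skeletal muscle (1107 bp) with a 2 kb window, for skeletal muscle with 5 kb (1703 bp), for erythroid cells (331 bp), macrophages (269.5 bp) and bone (1773 bp) against CpG-matched lists, and for bone (7335 bp) and gut, lung and pancreas (3041 bp) against marked genes. Promoter share turned for skeletal muscle with 500 bp (64.0%) and at a −log10 q of at least 5 (52.0%), for heart with any annotated start (69.4%), and against CpG-matched lists for erythroid cells (31.6%), bone (53.8%) and central neurons (84.0%). Ratios crossed 1 for the homeobox (0.915), SOX (0.942), LEF/TCF (0.963), GATA (0.685) and GLI (1.18) sequences without GC matching, MEIS (0.999) and GATA (0.999) at a −log10 q of at least 5, and HNF4 with 75 bp (1.33) and from 0.95 to 1.20 between replicates. Leaving out the settings with 1 replicate, single lists and sequences kept their direction and call in 108 of 131 alternatives for covered length, 110 of 132 for promoter share and 40 of 57 for sequence ratios. Surface ectoderm lost its call for promoter share with a 500 bp window (84.1%) and at a −log10 q of at least 5 (86.4%), and cartilage at 5 (80.8%).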

Other observations

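These values were sought after the report's results had been seen, and no explanation was tested for them. Long stretches without protein-coding genes differed widely in H3K4me2. Of 728 such intervals of at least 500 kb, the median was covered over 0.17% (mean of the replicates) and 144 had no covered base. The interval between Atp5g3 and Lnpk on the 5′ side of the HoxD cluster, a regulatory region known to act on HoxD in the digits, ranked 3rd with 4.24 ± 0.387% covered (SD, n = 2; chromosome 2, 73911327 to 74520290, 32 replicated peaks). The interval between Mtx2 and Hnrnpa3 on its 3′ side, known to act in the proximal limb, ranked 10th with 3.35 ± 0.194% (chromosome 2, 74878432 to 75659260, 34 replicated peaks). The most covered was the interval between Ubash3b and Sorl1 on chromosome 9, with 6.46 ± 0.0063%, followed by that between Npvf and Nfe2l3 on chromosome 6 with 4.92 ± 0.308%. The interval before Tbx3, a regulator of digit identity, had 3.21 ± 0.052%, that between Irx3 and Irx5, limb bud patterning genes, 3.18 ± 0.097%, and that beside Spry2, an inhibitor of FGF signalling, 3.77 ± 0.151%.

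Distal peaks within 50 kb of the gene start were also unevenly spread over the lists. Limb patterning regulators had a median of 7 ± 0.707 distal peaks, hedgehog, FGF, BMP and Wnt genes 6 ± 1.41, skeletal muscle genes 5 ± 1.41, tendon genes 4.5 ± 0.707 and cartilage genes 4.25 ± 0.354, against 1 for all protein-coding genes. Skeletal muscle genes thus had more distal peaks than nearly all random lists, at percentiles 99.975 and 100, while their promoter share did not pass the test. Lists of other tissues were not uniformly low. Gut, lung and pancreas genes had 3.25 ± 0.354 (percentiles 99.775 and 99.075), macrophage genes 3.5 and 2 in replicates 1 and 2 (99.825 and 84.675), heart genes 2.25 ± 0.354 and germ cell and central neuron genes 2 in both replicates, while erythroid and olfactory receptor genes had a median of 0 and liver genes 1. HoxC genes had a median of 24 in both replicates, HoxB genes 12.5 ± 0.707, HoxD genes 8 ± 1.41 and HoxA genes 5.5 ± 0.707, where a cluster marked without breaks holds fewer separate peaks. Neighbouring Hox genes share much of these windows, so they count many of the same peaks. In the replicated list single HoxC genes had 8 to 14 distal peaks and HoxB genes 4 to 10.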
